A study of Mus musculus with 2 samples.

How the data were processed

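The measurements were spatial gene expression libraries (10x Genomics Visium, in which a tissue section is laid on a slide of barcoded spots and polyadenylated RNA is captured spot by spot) from tibialis anterior muscle of C57BL/6 mice. Per the labels' protocols, the sciatic nerve was crushed in mice aged 3 months, and fresh-frozen muscle was cut into sections of 10 µm. There was 1 library from 3 d after the crush and 1 library from 30 d after it. Both files carried the same slide name, and the libraries came from different capture areas, so capture area, section and animal cannot be separated from the time point. The design text describes these samples as replicates of samples published earlier, which were not analysed here.

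The deposited values were raw UMI counts per gene and spot barcode, made by the authors with Space Ranger on genome build mm10, per the submitters' processing notes. The version of Space Ranger is not given in the sources used here. A UMI marks 1 captured molecule, so a count is of molecules and not of reads. The deposited count matrices were filtered to 945 barcodes at 3 d and 632 at 30 d, the same numbers as the positions flagged as tissue in the alignment files. Those files do not pair positions with barcodes, so no value was mapped onto the section. All spots were kept, and the main results used no further filter on spots. The matrices held 32285 features, of which 40 repeated the symbol of another, and the row with the most UMIs was used for such a symbol. Gene coordinates are from the RefSeq table of GRCm38, the assembly of mm10, which matched 10584 of the 10738 genes with at least 20 UMIs by symbol.

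UMIs were summed over the spots of a library and divided by the library total, as CPM (counts scaled to a common library total). With 1 library per group there was no test between groups, and no p-value was computed. The only standard errors were of counting, within the interval of a difference of 2 log2 ratios. Each CPM has an exact Poisson interval, and each log2 ratio of 3 d over 30 d CPM an exact conditional binomial (Clopper-Pearson) interval, both at the 95% level. These intervals cover counting error only, and not the spread between animals or sections. A count of 0 was replaced by a floor of 3 counts in that library, and the ratio then depends on that floor. The number of genes at least 2-fold apart was taken among genes with at least 100 UMIs over both libraries. A member of a list was called higher or lower when it was at least 1.5-fold apart and its interval excluded no difference.

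Before the data were examined, 36 gene lists were fixed, 24 of pathways and complexes and 12 of marker genes of cell types or sex. For members with at least 20 UMIs over both libraries, the median log2 ratio of a list was set against 10000 random lists of the same size, matched over 20 bins of mean CPM. A list with at least 3 measured members was called apart below the 2.5th or above the 97.5th percentile, as a description of these libraries. The named genes followed a rule also fixed beforehand. It took the 12 genes in each direction with the interval bound farthest from no difference, leaving out mitochondrially encoded, ribosomal protein, clone-named and sex-linked genes. It also took the measured genes of polyamine synthesis, catabolism, antizymes and transport, a set of denervation and myosin genes, and up to 4 members of each other list together with its most abundant member. Some genes that the rule takes are not reported here. The genes that describe a cluster were picked from its 10 leading genes after their values were seen. Other genes named outside the rule were also chosen after their values were seen, and this is said where they appear.

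Spots were also assigned to the adult myosin heavy chain gene (Myh4, Myh1, Myh2 or Myh7) with the most UMIs in the spot. A spot whose highest gene had under 5 UMIs, or was tied, stayed unassigned, and only classes of at least 20 spots were used. These classes are ranges of a mixed signal and not fibre types, since a spot can hold several fibres and other cells. A difference of 2 log2 ratios has an approximate (Wald) interval at the same level. Spots of each library were clustered separately with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, resolution 0.5). Clusters are described as regions by their leading genes, and their sizes are not compared between libraries. No doublet caller was run, since a spot is not a cell. Shares of spots with a UMI were taken after each spot was thinned to 2000 UMIs.

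The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and TMM factors came from edgeR 4.0.16 in R 4.3.3. The ratio and list steps were tested on simulated data with the real means and library totals, for the comparison of 3 d with 30 d over 6565 genes. Of 100 genes changed 2-fold, 96% were called in the right direction, and of 100 changed 4-fold, 100% were. Of the unchanged genes, 0.88% were called. These genes had equal mean CPM in both libraries, with counts drawn from the Poisson model. The real median gene lay at a log2 ratio of 1.02, so that rate does not carry over to the calls in CPM. Of 1000 unchanged lists of 12 genes, 60 were called apart. Their members were random genes drawn independently, which members of 1 pathway need not be. The alternatives fixed beforehand were TMM scaling, totals without mitochondrially encoded genes, median-ratio size factors, the mean of per-spot CPM, spots with at least 1000 UMIs, Myh4-led spots, leaving out the 10% of spots richest in marker UMIs, and thinning the 30 d library. Other alternatives were UMI minimums of 30 and 300 for the gene count and of 100 and 5 for the lists, spots with a clear leading myosin, cluster resolutions of 0.3 and 1.0, and thinning to 1000 UMIs.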

Results

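Spatial expression libraries were compared from tibialis anterior, a fast muscle of the lower leg, of C57BL/6 mice at 3 d and at 30 d after sciatic nerve crush. A crush cuts off nerve supply for a time while leaving the nerve sheath for regrowth. Each time point had 1 library from 1 section, so no difference below has a replicate check, and each interval covers counting error only. Both libraries came after a crush and no uninjured muscle was compared, so neither time point is a baseline. The 3 d library held 945 spots and 4905608 UMIs, with a median of 5065 UMIs per spot. The 30 d library held 632 spots and 5637860 UMIs, with a median of 8735. Mitochondrially encoded genes took 24.0% of UMIs at 3 d and 32.6% at 30 d. The 50 most abundant genes took 43.6% and 61.6%. With each spot thinned to 2000 UMIs, the median number of genes per spot was 861 at 3 d and 590 at 30 d. Gm42418, a gene model that overlaps ribosomal RNA sequence and was named after its values were seen, took 3.62% of UMIs at 3 d and 6.09% at 30 d.

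The genes farthest apart between the time points were, at 3 d, genes of denervated muscle and, at 30 d, genes of mature muscle. Ankrd1, a sarcomere-associated stress protein, had 2338 CPM at 3 d and 0.532 CPM at 30 d, from 11468 and 3 UMIs, a log2 ratio of 12.10 (95% interval 10.55 to 14.38). Myog, a transcription factor of muscle differentiation, had 595 and 1.24 CPM, a log2 ratio of 8.91 (7.86 to 10.22). Chrng, the fetal subunit of the acetylcholine receptor, had 460 UMIs at 3 d and 0 at 30 d. With the floor of 3 counts in place of 0 it was 176-fold higher at 3 d. The 95% interval of its log2 ratio ran upwards from 7.16. Krt18, Rrad, Srrm4os, Ces2c, S100a8, Gdf5, Krt8 and Runx1 were also among the 12 genes ranked highest at 3 d. At 30 d, Mettl21c had 93.8 CPM against 1.83 at 3 d, a log2 ratio of -5.68 (-6.81 to -4.74). Mlf1, Smco1, Kcng4, Perm1, Aqp4, Kcnc1, Ky, Actc1, Mir133a-1hg and Tmem233 were also among the 12 ranked highest at 30 d.

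Of 6478 genes with at least 100 UMIs, 3284 were at least 2-fold higher at 3 d, 332 were at least 2-fold lower and 2862 lay between. The median gene had a log2 ratio of 1.02, so a gene with equal CPM in both libraries lay below most genes. Relative to that median, 926 genes were at least 2-fold higher at 3 d and 1086 lower. Higher genes made up 90.8% of the genes 2-fold apart in CPM, 50.5% after TMM scaling and 48.9% with median-ratio size factors. Ratios are of CPM unless stated, and counts of list members are given in CPM and then relative to the median gene. Of 34 lists with a percentile, 13 were called higher at 3 d, 6 lower and 15 not apart. The medians of these 19 called lists kept their sign under all 4 other scalings.

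**Figure D1:**
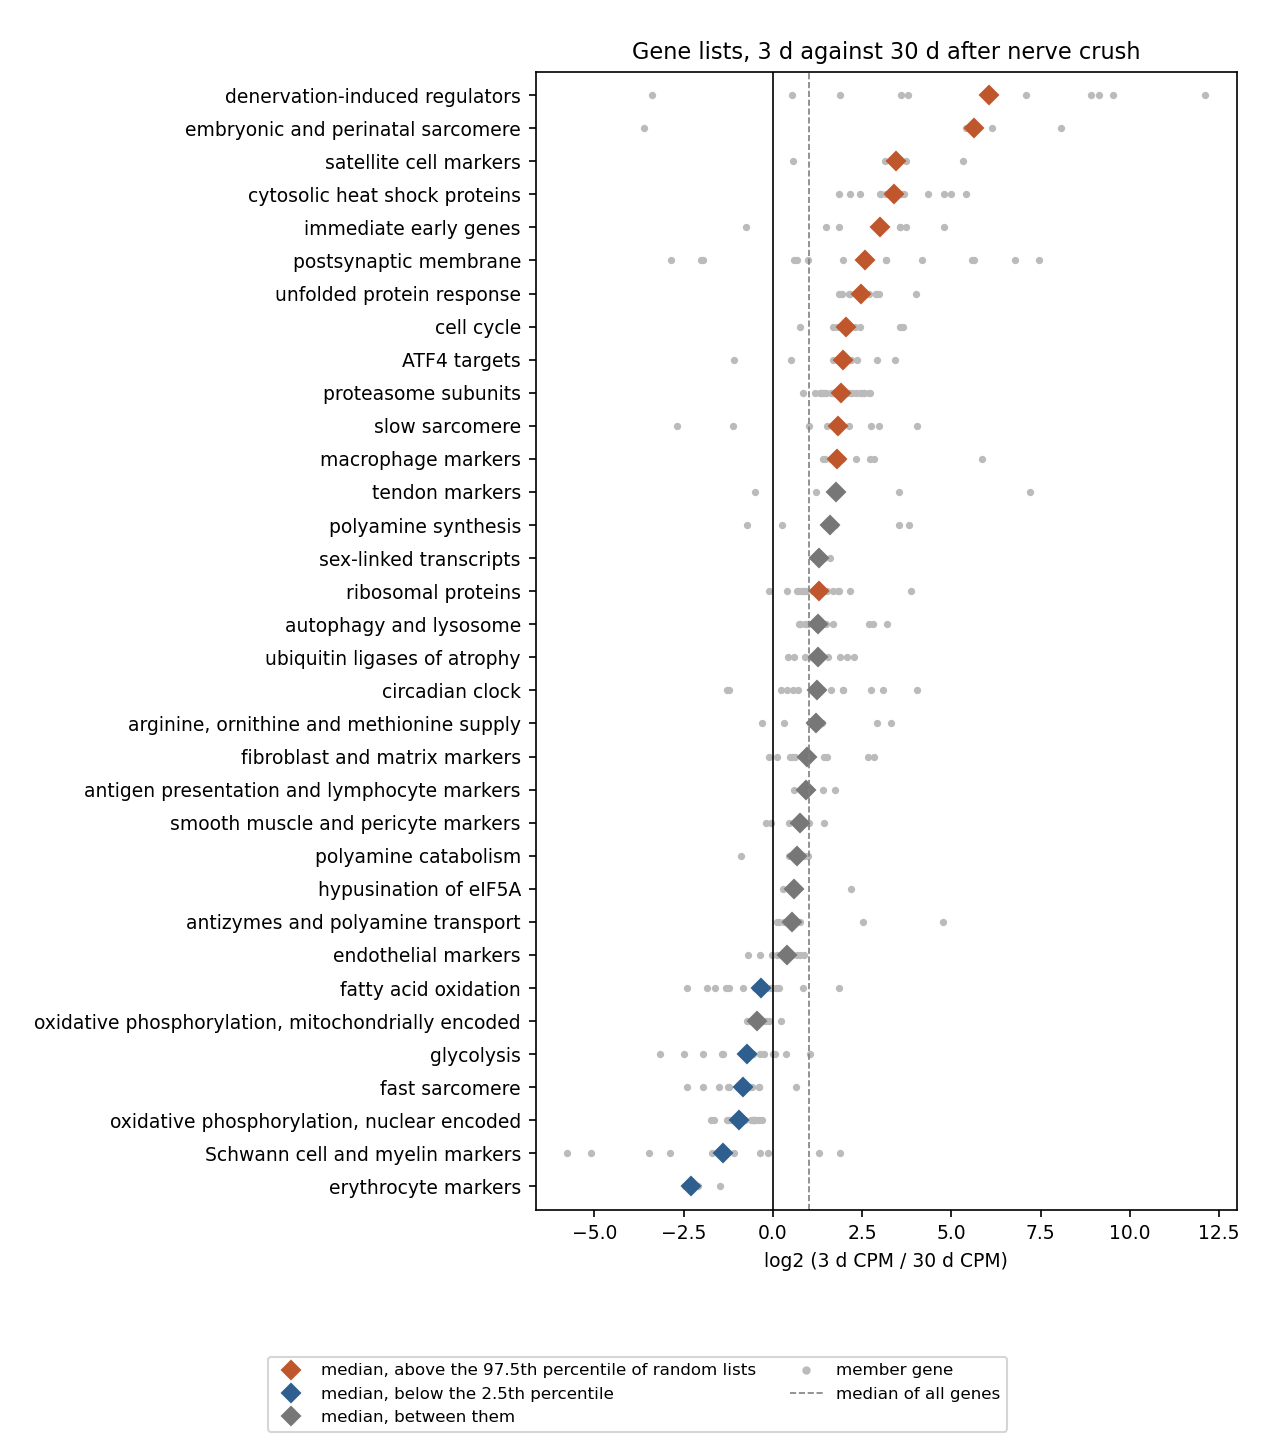
Log2 ratios of 3 d over 30 d CPM (horizontal axis) for the members of each gene list with a percentile (grey points, genes with at least 20 UMIs) and their median (diamonds, coloured by percentile among random lists). The solid line marks equal CPM and the dashed line the median gene at 1.02; medians run from -2.30 for erythrocyte markers to 6.05 for denervation-induced regulators.

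Genes of the denervated muscle membrane were higher at 3 d. The list of denervation-induced regulators had a median log2 ratio of 6.05 (percentile 100 of random lists), with 10 of 12 members higher and 1 lower, the same numbers relative to the median gene. Gadd45a, a stress-induced growth regulator, had 851 CPM at 3 d and 13.1 at 30 d, and Runx1, a transcription factor, had 410 and 3.02. The lower member was Dach2, named after its values were seen, with 0 UMIs at 3 d and 36 at 30 d. The list's name was set beforehand, and whether denervation raises or lowers each member was not checked, so Dach2 is not read as an exception. The postsynaptic list had a median of 2.57 (percentile 100), with 10 of 14 members higher and 3 lower in CPM, and 8 higher and 3 lower relative to the median gene. Chrna1, a receptor subunit of fetal and adult muscle, had a log2 ratio of 5.59 (5.20 to 6.00), and Musk, the kinase that organises the synapse, one of 6.77 (4.90 to 9.83) from 190 and 2 UMIs. The 3 lower members were Chrne, the adult receptor subunit (-1.95, -3.05 to -0.99), Ache, which breaks down acetylcholine (9 against 42 UMIs), and Colq, which anchors that enzyme (0 against 25 UMIs), the latter 2 named after their values were seen. The embryonic and perinatal sarcomere list had a median of 5.63 (percentile 100), with 4 of 5 members higher and 1 lower on either scale. Myh3, embryonic myosin, had 465 and 2 UMIs, a log2 ratio of 8.06 (6.20 to 11.11), and Actc1, cardiac actin, was lower at -3.61 (-3.83 to -3.41). Perinatal myosin Myh8 had 5 and 8 UMIs.

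Chrna1, Myog and 4 other genes tied to the synapse were followed spot by spot, and Chrna1 and Myog were found in the most spots at 3 d. With spots thinned to 2000 UMIs, which left out 197 spots at 3 d and 96 at 30 d, Chrna1 had a UMI in 54.0% of spots at 3 d (exact binomial 50.4 to 57.6) and in 1.68% at 30 d (0.771 to 3.16). Unthinned shares were 69.0% and 5.38%, and with 1000 UMIs per spot 29.9% and 1.29%. Myog had a UMI in 64.7% of thinned spots at 3 d and in 0.187% at 30 d, in 75.2% and 1.11% unthinned, and in 35.3% and 0.162% with 1000 UMIs. Chrng was found in 14.4% at 3 d and in 0 of 536 spots at 30 d. There the floor of 3 counts is 0.560%, and the exact binomial interval reaches 0.686%. With 1000 UMIs its share at 3 d was 6.74%. Chrnd was found in 112 of 748 spots at 3 d and 2 of 536 at 30 d thinned to 2000 UMIs, Musk in 6.02% at 3 d and Ache in 0.134% and 1.12%.

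**Figure D2:**
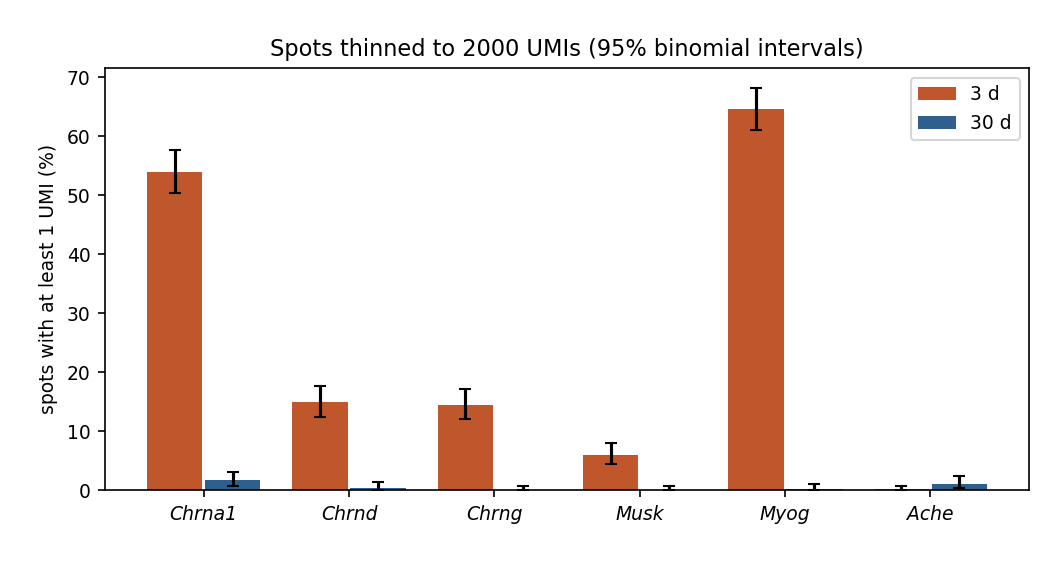
Share of spots (percent) with at least 1 UMI of 5 synaptic genes and Myog, after thinning each spot to 2000 UMIs, at 3 d (748 spots) and 30 d (536 spots), with exact binomial 95% intervals. Chrna1 was found in 54.0% of spots at 3 d and 1.68% at 30 d, and Ache in 0.134% and 1.12%.

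The series title names polyamine metabolism, and the genes of that pathway differed in direction. Odc1, the rate-limiting enzyme of polyamine synthesis (ENSMUSG00000011179; chromosome 12, 17544808 to 17551502, mm10), had 297 CPM at 3 d (282 to 312) and 25.4 at 30 d (21.4 to 29.9), a log2 ratio of 3.55 (3.30 to 3.81). Srm, spermidine synthase (chromosome 4, 148591513 to 148594619), had 40.0 and 2.84 CPM, a ratio of 3.82 (3.08 to 4.65). Sms, spermine synthase, had a ratio of 1.75 (1.49 to 2.01), and Azin1, an antizyme inhibitor, 1.46 (1.12 to 1.82). Amd1, which makes the decarboxylated S-adenosylmethionine that both synthases use (ENSMUSG00000075232; chromosome 10, 40287458 to 40302188), went the other way, with 30.0 CPM at 3 d (25.3 to 35.2) and 49.7 at 30 d (44.0 to 55.8), a ratio of -0.73 (-1.03 to -0.44). Amd2, a near copy of Amd1 whose counts may be shared with it, had 0.25 (-0.28 to 0.78). Among catabolic genes, Smox, spermine oxidase, had 16.9 and 31.6 CPM, a ratio of -0.90 (-1.29 to -0.52), and Sat1, which acetylates spermidine and spermine, had 0.99 (0.62 to 1.36), close to the median gene. Sat2 had 19 and 12 UMIs and Paox 12 and 10, and no difference was detectable at this depth.

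Among genes of polyamine transport, Atp13a3, a polyamine transporter (chromosome 16, 30312423 to 30388871), had 227 CPM at 3 d and 8.34 at 30 d, a log2 ratio of 4.77 (4.35 to 5.22). Slc3a2, a heavy chain of amino acid transporters, had 2.51 (2.11 to 2.93). Oaz1 and Oaz2, the antizymes that restrain Odc1, had 0.13 (0.03 to 0.22) and 0.18 (-0.08 to 0.45), which are -0.90 and -0.84 relative to the median gene. Atp13a2 had 0.77 (0.11 to 1.45), and its sign turned under TMM scaling and median-ratio size factors, to -0.18 and -0.21. Slc18b1 had 14 and 13 UMIs. Eif5a, the protein modified with spermidine, had 2.18 (2.06 to 2.29), while its modifying enzymes Dhps and Dohh had 0.60 and 0.28, which are -0.42 and -0.74 relative to the median gene. The sign of Dhps also turned under those scalings. No polyamine list was called apart. Synthesis had a percentile of 90.7 (4 of 6 higher, 1 lower; 3 and 2 relative), catabolism 26.2 (1 of 4 higher, 1 lower; 0 and 1 relative), and antizymes and transport 20.2 (3 of 6 higher, 0 lower; 2 and 2 relative). Hypusination had 29.7 (2 of 3 higher, 0 lower; 1 and 1 relative), and arginine, ornithine and methionine supply 63.9 (4 of 6 higher, 0 lower; 2 and 2 relative). The medians of catabolism, antizymes and hypusination turned negative under TMM scaling and median-ratio size factors.

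**Figure D3:**
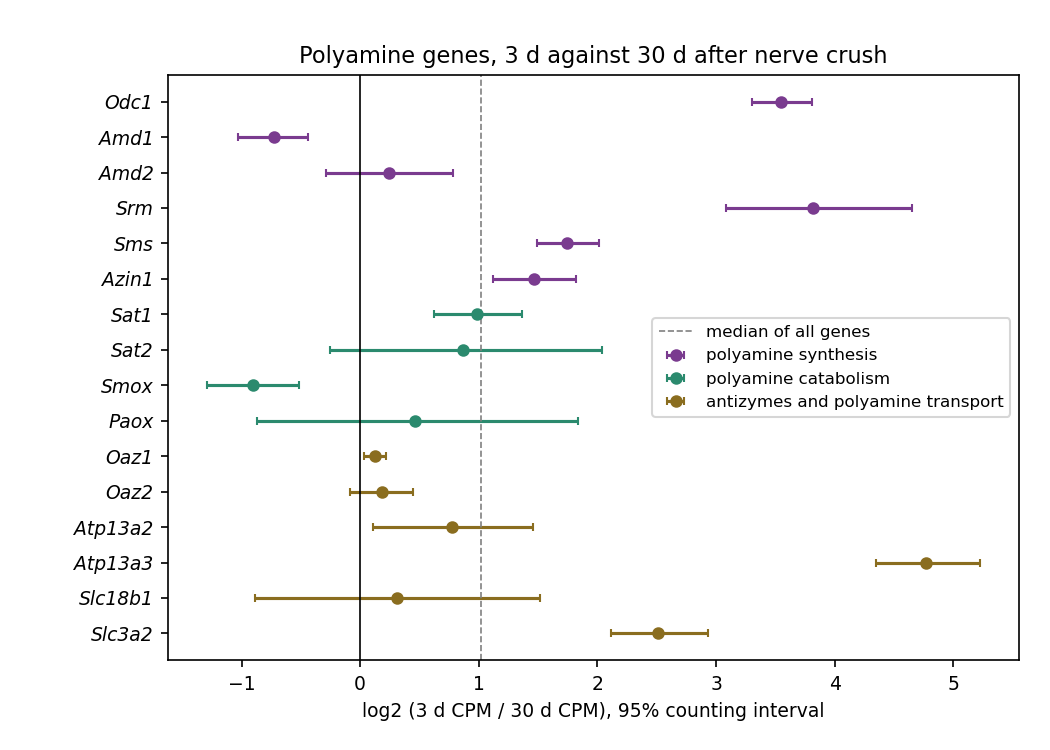
Log2 ratio of 3 d over 30 d CPM (horizontal axis) of each measured polyamine gene, with exact 95% counting intervals, coloured by list. Odc1, Srm and Atp13a3 lie above 3, Amd1 and Smox lie below 0, and the dashed line marks the median gene at 1.02.

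Lists of protein folding and of the proteasome were called higher at 3 d. All 12 heat shock genes were higher on either scale (median 3.40, percentile 100), with Cryab, a small heat shock protein, at 8345 and 677 CPM and Hspb8 at 2761 and 65.1. All 12 genes of the unfolded protein response were higher on either scale (median 2.48, percentile 100), and Hspa5, the chaperone of the endoplasmic reticulum, had 549 and 85.3 CPM. All 30 proteasome subunits were higher in CPM and 22 relative to the median gene (median 1.90, percentile 100), with Psmc4 at 2.72 (2.48 to 2.98). ATF4 targets had a median of 1.98 (percentile 99.6; 8 of 10 higher and 1 lower, 7 and 1 relative). This list's percentile was 96.0 when genes needed 100 UMIs. Immediate early genes had 3.02 (percentile 100; 8 of 9 higher and 1 lower, 7 and 1 relative), with Junb at 104 and 3.72 CPM. Cell cycle genes had 2.05 (percentile 99.3; 9 of 9 higher, 4 relative) and ribosomal proteins 1.28 (percentile 99.9; 24 of 26 higher, 5 higher and 2 lower relative).

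The ubiquitin ligases Fbxo32 and Trim63, markers of muscle wasting, had 434 and 89.4 CPM and 526 and 125 CPM, log2 ratios of 2.28 (2.14 to 2.42) and 2.07 (1.95 to 2.19). Their list was not called apart (percentile 78.3; 8 of 9 higher, 3 relative), and neither was autophagy and lysosome (92.5; 16 of 16 higher, 4 relative), where Sqstm1, an autophagy receptor, had 808 and 125 CPM. Circadian clock genes were not apart as a list (73.4; 9 of 14 higher and 2 lower, 6 and 4 relative), although Per1 had 93.4 and 5.68 CPM.

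The lists of nuclear-encoded oxidative phosphorylation, glycolysis, fatty acid oxidation and the fast sarcomere were called lower at 3 d. Nuclear-encoded oxidative phosphorylation had a median of -0.96 (percentile 0.01), with 18 of 26 members lower, and 26 relative to the median gene. Cox7a1, a muscle subunit of cytochrome oxidase, had 725 and 2428 CPM. Glycolysis had -0.73 (percentile 0.61; 8 of 15 lower and 1 higher, 14 and 0 relative), with Tpi1 at -3.15 (-3.27 to -3.04) and Aldoa, its most abundant member, at 0.05 (0.03 to 0.07). Fatty acid oxidation had -0.32 (percentile 0.47; 6 of 15 lower and 2 higher, 13 and 1 relative). Fabp3, which carries fatty acids, had -2.41 (-2.52 to -2.31), and Pdk4, which restrains glucose oxidation, was higher at 1.86 (1.68 to 2.05). The fast sarcomere list had -0.84 (percentile 1.07; 9 of 12 lower and 1 higher, 11 and 0 relative), with Myh4 at 3704 and 10580.1 CPM and Myh1 at -2.41 (-2.44 to -2.38). Myh2, a fast myosin outside that list, had -2.16 (-2.30 to -2.03). The fast sarcomere's percentile was 3.17 when genes needed 100 UMIs. Slow sarcomere genes were higher (median 1.83, percentile 97.8; 6 of 8 higher and 2 lower, 4 and 2 relative), with Tnni1 at 72 and 5 UMIs, Myh7 at 15 and 6, and Myl3 lower at -2.67 (-2.92 to -2.43). When genes needed 100 UMIs, 5 members remained and the percentile was 48.5. The mitochondrially encoded list was not apart (percentile 9.03; 3 of 13 lower, 13 relative).

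Markers of other cell types differed as well. Macrophage markers were higher at 3 d (median 1.79, percentile 99.0; 12 of 12 higher, 9 relative), with Lyz2 at 149 and 48.4 CPM and Cd68 at 71.8 and 1.24. The percentile was 94.8 with each spot given the same weight. Satellite cell markers were higher (median 3.44, percentile 99.9, 3 of 4 higher on either scale), with Myod1 at 347 and 8.69 CPM. Of the 7 listed members 4 were measured, and Pax7, Myf5 and Calcr were not. Myod1 held 1702 of the list's 2107 UMIs at 3 d. This list therefore does not show whether satellite cells were more numerous. Schwann cell and myelin markers were lower (median -1.40, percentile 0; 6 of 10 lower and 1 higher, 8 and 0 relative), with Mbp at 7.75 and 56.6 CPM. All 5 erythrocyte markers were lower (median -2.30, percentile 0), with Hbb-bs at 693 and 3835 CPM. The lists not apart were endothelial markers (percentile 4.43), smooth muscle and pericyte markers (26.9), fibroblast and matrix markers (61.3), tendon markers (90.8), antigen presentation and lymphocyte markers (46.3) and sex-linked transcripts (69.6). Medians of the endothelial, smooth muscle, fibroblast and antigen presentation lists turned negative under TMM scaling and median-ratio size factors. Neutrophil markers had 1 measured member and adipocyte markers 2, too few for a percentile. S100a8, the measured neutrophil marker, had 981 UMIs at 3 d and 4 at 30 d.

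Spots were then set side by side by their leading myosin gene, to ask whether polyamine genes differed between parts of a section. At 3 d, 736 spots were led by Myh4, the myosin of the fastest fibres, 181 by Myh1, 3 by Myh2, and 25 were unassigned. At 30 d, 376 were led by Myh4, 249 by Myh1, and 7 were unassigned. The leading gene had under 1.5 times the UMIs of the next in 92 Myh4-led and 50 Myh1-led spots at 3 d, and in 92 and 67 at 30 d. Myh4-led spots had a median of 4041.5 UMIs at 3 d and 5161 at 30 d, and Myh1-led spots 8054 and 12516. At 30 d, Amd1 had 74.9 CPM in Myh4-led spots (194 UMIs) and 28.2 in Myh1-led spots (85 UMIs), a log2 ratio of Myh1-led over Myh4-led of -1.41 (-1.80 to -1.04). At 3 d it had 31.3 and 26.8 CPM, a ratio of -0.22 (-0.79 to 0.32). Amd2 had -2.07 (-3.08 to -1.16) at 30 d and -0.31 (-1.26 to 0.57) at 3 d, Smox -0.71 (-1.16 to -0.27) and -0.16 (-0.92 to 0.56), and Atp13a3 -1.56 (-2.61 to -0.60) and 0.09 (-0.10 to 0.27). At 30 d, 6 polyamine genes were at least 1.5-fold higher in Myh4-led spots with an interval excluding no difference. Besides Amd1, Amd2, Smox and Atp13a3 these were Sms and Azin1. At 3 d there were 0. Odc1 was under that cut at both times, with -0.40 (-0.90 to 0.09) at 30 d and -0.43 (-0.61 to -0.25) at 3 d. The number at 30 d was 3 with totals taken without mitochondrially encoded genes, namely Amd1, Amd2 and Atp13a3. Atp13a3 had 33 UMIs in Myh4-led and 13 in Myh1-led spots at 30 d. The share of all genes that passed this rule was not taken. A shift of most genes between the classes is therefore not excluded as a source of these numbers.

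The 3 d to 30 d ratio was then taken within each class. Amd1 had -1.26 (-1.62 to -0.91) in Myh4-led spots and -0.07 (-0.66 to 0.49) in Myh1-led spots, a difference of 1.19 (0.54 to 1.83). Atp13a3 had 4.15 and 5.80, a difference of 1.65 (0.71 to 2.60). The interval of the difference held 0 for Smox (0.55, -0.26 to 1.37), Sms (0.40, -0.13 to 0.93) and Azin1 (0.23, -0.50 to 0.96). Odc1 had 3.46 and 3.44, a difference of -0.03 (-0.53 to 0.48), and Srm 3.89 and 3.74, with intervals of 2.81 to 5.24 and 2.72 to 4.94. The myosin Myh2 was 793 CPM in Myh1-led and 151 in Myh4-led spots at 30 d, and 111 and 95.5 at 3 d. Fbxo32 and Trim63 were higher in Myh4-led spots at 3 d, with Myh1-led over Myh4-led ratios of -0.82 (-0.98 to -0.66) and -0.75 (-0.89 to -0.61). Within Myh4-led spots the median gene lay at 0.95 and within Myh1-led spots at 0.83.

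**Figure D4:**
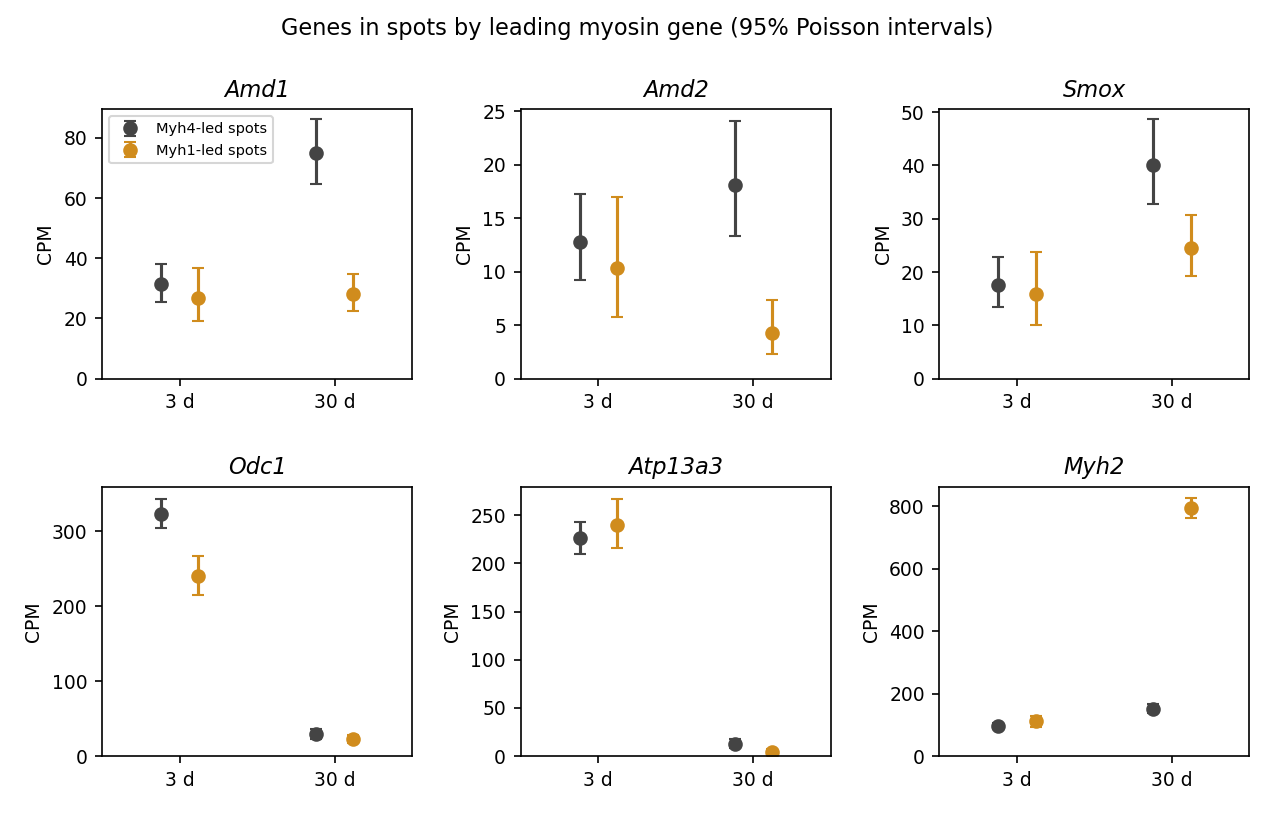
CPM (vertical axes, from 0) of 6 genes in spots led by Myh4 and by Myh1 at 3 d and 30 d, with exact Poisson 95% intervals. At 30 d, Amd1 had 74.9 CPM in Myh4-led and 28.2 in Myh1-led spots, against 31.3 and 26.8 at 3 d.

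Clustering gave 4 regions at 3 d and 3 at 30 d. At 3 d, the region of 311 spots led by haemoglobin genes and Actc1 had a median of 1967 UMIs per spot, against 7893 for the 237 spots led by Myl3, 3846.5 for the 202 led by Ppargc1a, Plin4 and Fbxo32, and 7543 for the 195 led by Mmp19, Tnc and Postn. Odc1 had 334, 252, 296 and 334 CPM in these regions. Atp13a3 had 228, 244, 104 and 271 CPM. At 30 d, regions were led by Myl3 and Myh2 (258 spots), by Gm42418 and Lars2 (227 spots, median 3528 UMIs) and by S100a4 and Mbp (147 spots). Amd1 had 28.0 CPM (22.3 to 34.8), 59.0 (46.3 to 74.1) and 85.1 (70.8 to 101) in them. The number of regions changed with the resolution.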

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

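The 3 d to 30 d ratios of 5 genes had opposite signs in the Myh4-led and the Myh1-led spots. With 1 library per time point, none of these differences was tested between groups, and the intervals are of counting error. Picking genes by opposite signs favours large differences, and the intervals make no allowance for that or for the number of genes looked at. Amd2 had a log2 ratio of -0.51 in Myh4-led and 1.26 in Myh1-led spots, a difference of 1.77 (0.54 to 3.00). Slc18b1 had -0.76 and 1.54, a difference of 2.30 (0.05 to 4.55), from at most 8 UMIs in a class. For the other genes the interval of the difference held 0: Paox with -0.77 (-3.62 to 2.07), Oaz2 with 0.44 (-0.11 to 0.99) and Dohh with 0.71 (-0.07 to 1.48). The median gene lay at 0.95 in Myh4-led and 0.83 in Myh1-led spots. Relative to these medians the ratios of Paox, Oaz2 and Dohh were negative in both classes, while Amd2 and Slc18b1 kept opposite signs. In Myh1-led spots the counting interval of each of the 5 genes held the median, as did those of Paox and Slc18b1 in Myh4-led spots.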

How the results depend on the processing

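The alternatives in this part were all planned. No paired analysis was possible because each group has 1 library, and no library could be left out. Of 233 list values under alternatives that could move a percentile, 226 kept their call. Spots with at least 1000 UMIs were 920 of 945 at 3 d and 619 of 632 at 30 d. Thinning the 30 d library to the 3 d total moved the median log2 ratio by -0.0008. These 2 alternatives changed the data little, so most calls under them had little room to change. TMM scaling, median-ratio size factors and totals without mitochondrially encoded genes shift every gene alike, so a percentile could not move under them. The first 2 changed the number of genes at least 2-fold apart from 3284 higher and 332 lower to 1018 and 997, and to 982 and 1028, by construction. With UMI minimums of 30 and 300, 5127 and 1353 genes were higher, since other numbers of genes enter. With each spot given the same weight, the percentile of slow sarcomere genes was 97.3, of macrophage markers 94.8 and of endothelial markers 0.89; within Myh4-led spots that of endothelial markers was 2.22. The cause was not tested. With 100 UMIs per gene, the percentile was 3.17 for the fast sarcomere, whose 12 members all stayed, 96.0 for ATF4 targets with 6 members and 48.5 for the slow sarcomere with 5, on the other side of the middle. Under TMM scaling and median-ratio size factors, which lower every ratio alike, any ratio between 0 and about 0.95 changed sign, and of the named genes called higher these were Atp13a2 (-0.18 and -0.21), Dhps (-0.35 and -0.38), H2-Aa (-0.0104 and -0.0395), H2-Ab1 (-0.0622 and -0.0914), Cldn5 (-0.0688 and -0.0980), Flt1 (-0.18 and -0.21) and Myh11 (-0.18 and -0.21). Of 1448 gene values, 437 others lay outside the counting interval of the reported value. The polyamine genes 1.5-fold apart between classes at 30 d were 3, not 6, with totals without mitochondrially encoded genes. Clusters at 30 d were 2 at resolution 0.3 and 6 at 1.0, and at 3 d they were 2 at 0.3 and 7 at 1.0. Of 24 share values under other depths, 15 lay outside the interval of the reported share; at 3 d, thinning to 1000 UMIs gave 29.9% for Chrna1, 35.3% for Myog, 9.02% for Chrnd and 6.74% for Chrng, since a shallower spot holds fewer of its UMIs. Depth limits genes such as Paox, Sat2 and Slc18b1, with 31 UMIs or fewer.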

Other observations

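Chosen only after the result was seen were the tests of the abundant genes and of Amd1 and Amd2 added together, the use of 2 planned settings (no mitochondrially encoded genes, Myh4-led spots) as tests of the shift, and the look at single Schwann cell genes and at their sum without Art3.

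Some markers stood far from the rest of their lists. S100a8 had 981 UMIs at 3 d, while its usual partner S100a9, named after its values were seen, had 13. Cd68 had a log2 ratio of 5.85 (4.79 to 7.18), against a median of 1.79 for macrophage markers. Scx, a transcription factor of tendon, had 1035 UMIs at 3 d and 8 at 30 d, and was found in 30.1% of spots thinned to 2000 UMIs at 3 d. In the 4 regions at 3 d, in the order used above, Scx had 212, 213, 145 and 242 CPM and Cd68 87.9, 73.1, 42.8 and 76.4, whereas Lyz2 had 141, 98.7, 72.7 and 260 CPM. All 4 measured Y-linked genes were detected in both libraries and Xist, named after its values were seen, had 0 UMIs in each.

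The median gene was 2.03-fold higher at 3 d in CPM. A candidate explanation is that a few abundant genes took more of the 30 d counts. Leaving the 50 genes with most UMIs at 30 d out of the totals brought the median log2 ratio from 1.02 to 0.39 (0.35 to 0.42 over genes). These 50 genes thus account for part of the shift and not for all of it. The remainder depends on the cut of 50, and other cuts were not tried. Leaving out mitochondrially encoded genes gave 0.85, and taking Myh4-led spots alone gave 0.95, which argues against either as the whole cause. The 3 d library did hold a wider range of transcripts, with a median of 861 genes per spot at 2000 UMIs against 590 at 30 d. Whether that range comes from the muscle was not tested. Differences between animals, sections and capture areas stay open and untested.

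Amd1 was higher in Myh4-led than in Myh1-led spots at 30 d and not detectably so at 3 d. Some other genes, picked after their values were seen, also had smaller contrasts at 3 d. Their Myh1-led over Myh4-led ratios at 3 d and 30 d were 0.21 and 2.39 for Myh2, 0.09 and 0.70 for Fabp3, and 0.06 and 0.57 for Cpt1b. On the same side as Amd1 were Actn3 with -0.41 and -1.27, Pvalb with -0.52 and -1.19, and Mybpc2 with -0.84 and -1.31. Odc1 had -0.43 and -0.40, and Fbxo32 (-0.82 and -0.29) and Trim63 (-0.75 and -0.25) had larger contrasts at 3 d. A smaller contrast at 3 d was thus not particular to Amd1. Spots held a mean of 29.4 myosin UMIs at 3 d and 186 at 30 d, so noisier classes might have hidden the contrast at 3 d. The 30 d myosin UMIs were thinned to the 3 d mean, which bears on noisy calls only and leaves the 30 d regions as they were. After it, 78.3% of spots kept their class. The median Amd1 ratio over 20 draws was -1.44 (-1.58 to -1.28), below the 3 d interval of -0.79 to 0.32. In 30 d spots with at least 5000 UMIs it was -1.41 (-1.82 to -1.02), which argues against shallow spots, while reads shared between Amd1 and Amd2 stay open, since both were lower in Myh1-led spots and their sum, at -1.52 (-1.87 to -1.17), had to be so too. A lower Amd1 level in Myh4-led regions soon after denervation and a raised one at 30 d cannot be told apart without uninjured muscle. Both are hypotheses that these data leave open. Differences between animals, section planes and capture areas also stay open and cannot be separated from time here.

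Myelin genes were lower at 3 d, with 194 UMIs of 6 genes against 1661, a log2 ratio of -2.90 (-3.12 to -2.68). Less nerve in the 3 d section could give this, and it stays open. A panel of 7 genes taken as Schwann cell genes outside myelin, added together, had -0.63 (-0.85 to -0.41). But 3 of them were higher and 3 lower at 3 d with intervals excluding no difference, so their sum does not decide it. Spots hold muscle fibres as well, and whether these fibres also express the panel genes was not checked. Erbb3 had 1.99 (0.99 to 3.11), Sox2 3.90 (1.17 to 9.31) and Scn7a 1.34 (0.62 to 2.10), while Egfl8 had -2.54 (-4.07 to -1.29), Kcna1 -1.26 (-2.64 to -0.04) and Art3, with most of the UMIs, -1.16 (-1.45 to -0.88), and without Art3 the sum was 0.46 (0.07 to 0.86). The 10 richest spots held 54.9% of the myelin UMIs at 30 d, and without them the ratio was still -1.77 (-2.01 to -1.54), so a few spots over a nerve account for part of the difference only; a change of Schwann cell state after the crush stays open as a hypothesis, as do differences between animals and section planes.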
